A study of Mus musculus with 15 samples.

How the data were processed

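RNA sequencing of whole hearts from mouse embryos at E14.5 was analysed in 15 libraries: 7 labelled WT, 4 labelled Adamts16+/- and 4 labelled Adamts16+/H355Q. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit. The submitters' processing notes name fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2, without the role or order of each. The deposited table gives FPKM, fragments per kilobase of gene per 1e6 fragments, for 55335 mouse gene identifiers in each library. The tool that computed FPKM, the genome build and the annotation are not given in the sources used here. FPKM values are not counts, so no count model was used. Whether the libraries came from separate embryos or litters is not stated, so p-values measure the spread between these libraries.

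Gene symbols were matched to 55154 of the identifiers through GENCODE vM21, an annotation of the GRCm38 build. The low values of long genes were used to estimate what 1 fragment is worth in each library, which gave 37.7 to 59.0 M (1e6) implied fragments per library. Between 59.6% and 66.9% of these low values were whole multiples of that step within a tolerance of 0.1 step, so whole reads were not recovered. Pairwise correlations of the libraries lay between 0.951 and 0.986, and no 2 libraries were identical.

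Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with the variance trend, for 15172 genes with a mean of at least 0.5 FPKM. All 15 libraries entered 1 fit with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method, with a call at an adjusted p under 0.05. A fold change on this scale understates the change of low genes. Gene lists for pathways and cell types were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adamts16 lay below the filter and was tested with a two-sided exact permutation test on log2(FPKM + 0.5), adjusted over the 3 comparisons. The designs, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each comparison and direction, up to 10 called genes with the largest fold and a mean of at least 1 FPKM, leaving out symbols of numbered gene models, Rik and clone names and -ps pseudogenes; it went by symbol, so the annotated pseudogenes Hbb-bh0 and H3f3c stayed in. It added the list members with the smallest p, genes called alike in both comparisons against WT, and Fn1 and Sox9.

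The gene test was tested on simulated data with the real means and spreads of the 15172 genes, in which 50 genes per fold size were changed. For Adamts16+/- against WT it recovered 76% of 1.5-fold and 92% of 2-fold changes. For Adamts16+/H355Q against WT it recovered 80% and 88%, and for Adamts16+/- against Adamts16+/H355Q 58% and 92%. Of the unchanged genes 8, 9 and 15 were called in these 3 comparisons. Genes were simulated independently, so differences among the WT libraries that many genes share were left out. The rates may therefore not hold for the real libraries. Alternatives covered the pseudocount, the filter, scaling, variance and weighting options, covariates, the replicate number as a block, and leaving out each library in turn. After the data were examined, settings were added that left out WT libraries 5 to 7 or WT libraries 1 to 4, removed length and GC trends, kept protein-coding genes only, or used embryonic globins as a covariate. The WT libraries were set apart from each other by their expression, not by any label. Fits that compared these WT subsets with each other and with each genotype were run after the data were examined and then withdrawn, because the subsets were defined by the measured outcome. No result of those fits is given here, but the embryonic globin pattern and Pole3 were first noticed in them. The added settings that left out WT libraries 5 to 7 or 1 to 4 also set each genotype against 1 of these subsets. Their results are given only to show how far the main results depended on the WT libraries.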

Results

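Hearts of mouse embryos at E14.5 were profiled by RNA sequencing to compare WT animals with animals carrying a changed Adamts16 allele, which encodes a secreted metalloprotease of the extracellular matrix. There were 15 libraries, 7 labelled WT, 4 Adamts16+/- and 4 Adamts16+/H355Q. Whether a library held 1 heart or several is not stated in the labels, and 9 of the 15 had both Xist, expressed from the inactive X chromosome of females, and the Y-linked gene Ddx3y above 1 FPKM. In these 9 libraries Xist was at 11.6 to 56.2 FPKM and Ddx3y at 3.86 to 10.7 FPKM. Such values argue against a single embryo as the only source of each of those libraries. Each n and SD therefore counts libraries, not animals. The implied depth was 37.7 to 48.0 M fragments (M, 1e6) in the Adamts16+/- libraries, 51.1 to 59.0 M in the Adamts16+/H355Q libraries and 42.1 to 56.0 M in WT.

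Adamts16 itself was expressed at a low level in every library. The gene lies on chromosome 13 from 70727802 to 70841811 in GRCm38. Its level was 0.106 ± 0.0758 FPKM (SD, n = 7) in WT, 0.116 ± 0.0804 FPKM (SD, n = 4) in the libraries labelled Adamts16+/- and 0.104 ± 0.0267 FPKM (SD, n = 4) in the libraries labelled Adamts16+/H355Q. The 7 WT libraries held 0.0325, 0.0495, 0.0543, 0.0647, 0.167, 0.138 and 0.235 FPKM. The libraries labelled Adamts16+/- held 0.0897, 0.235, 0.0635 and 0.0747 FPKM, and those labelled Adamts16+/H355Q held 0.0677, 0.123, 0.125 and 0.101 FPKM. These levels correspond to about 11 to 79 fragments per library, 11 to 19 in WT libraries 1 to 4 and 53 to 79 in WT libraries 5 to 7. The log2 difference of Adamts16+/- from WT was 0.02, with a 95% limma interval from -0.22 to 0.27 and an exact permutation p of 0.842 (adjusted p = 0.976). A halving of the WT level would give -0.13 on this scale, which lies inside the interval, so a halving is not excluded. The limma SE was 0.116, against 0.0265 from counting error alone if fragments are independent. The difference was -0.15 with WT libraries 1 to 4 left out and 0.15 with WT libraries 5 to 7 left out, so its sign depended on the WT libraries used. The level therefore does not check the Adamts16+/- label.

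**Figure D1:**
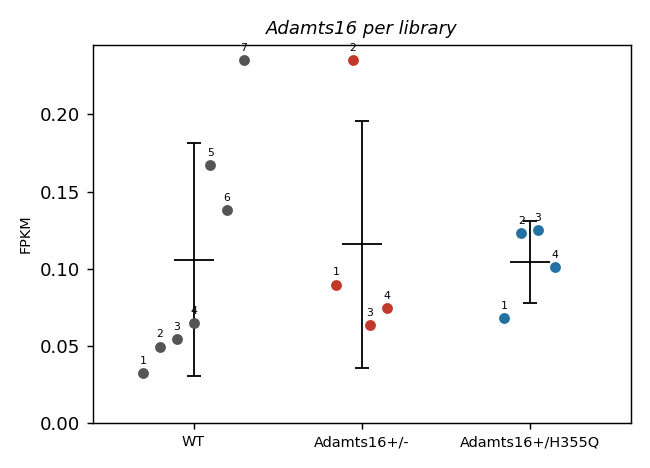
Adamts16 in FPKM (vertical axis, from 0) for each library, numbered by replicate, in the 3 genotypes, with the group mean and SD as a bar. The groups overlap, with means of 0.106, 0.116 and 0.104 FPKM.

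The WT libraries lay on both sides of the main axis of variation. The first principal component held 27.6% of the variance and placed WT libraries 1 to 4 between -19.6 and -12.2, beside the Adamts16+/- libraries at -18.7 to -11.8. WT libraries 5 to 7 lay between 8.0 and 36.1, beside the Adamts16+/H355Q libraries at 8.5 to 23.1. Fn1, which encodes the matrix protein fibronectin, was at 108, 110, 108 and 113 FPKM in WT libraries 1 to 4 and at 74.7, 62.9 and 57.1 FPKM in WT libraries 5 to 7. The mitochondrial transfer RNA gene mt-Tq was at 22.5 to 32.1 FPKM in WT libraries 1 to 4 and at 2.38 to 5.48 FPKM in WT libraries 5 to 7. The labels give no batch that separates these libraries. The annotated microRNA gene Mir6236 was at 54.2 to 116 FPKM in WT libraries 1 to 4 and at 3.75 to 9.74 FPKM in WT libraries 5 to 7. The genes mt-Tq and Mir6236 were picked for this description after their values were seen.

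**Figure D2:**
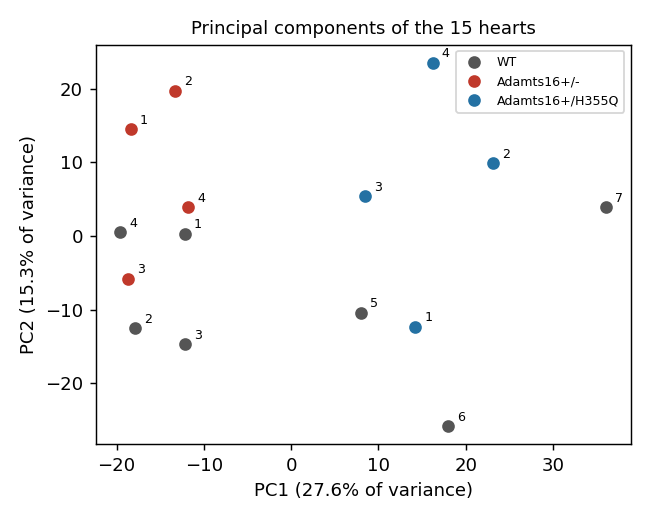
First (horizontal) and second (vertical) principal component of log2(FPKM + 0.5) over 15172 genes, with 1 point per library numbered by replicate. WT libraries lie on both sides of the first component, from -19.6 to 36.1.

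In Adamts16+/- hearts, the fatty acid genes Fabp4, Cd36, Fabp3 and Pdk4 and the muscle genes Ckm and Myom2 were lower than in WT, and the embryonic globin Hbb-bh1 was higher. Fabp4, a fatty acid binding protein, fell by 1.26 on the log2 scale (adjusted p = 0.0088), from 26.3 ± 4.82 (SD, n = 7) to 10.5 ± 1.04 FPKM (SD, n = 4). It was also below every WT library (21 to 32.8 FPKM) in Adamts16+/H355Q libraries 3 and 4 (16.7 and 17.4 FPKM). In Adamts16+/H355Q libraries 1 and 2 it was at 28 and 34.5 FPKM. Ckm, the muscle creatine kinase, fell by 1.54 (adjusted p = 0.0246), and Myom2, a protein of the sarcomere M-band, fell by 1.37 (adjusted p = 0.0121). The embryonic globin Hbb-bh1 was higher by 2.54 ± 0.54 (log2, SE; adjusted p = 0.0258), at 51.8 ± 3.96 FPKM (SD, n = 4) against 10.7 ± 7.06 FPKM (SD, n = 7). In limma, 417 of 15172 genes passed an adjusted p of 0.05, of which 238 were higher and 179 lower. The balance of directions depended on the scaling: 168 were higher and 209 lower with median of ratios scaling, 192 and 241 with quantile normalization, and 591 and 163 with TPM scaling. TPM scaling also changed which genes passed the filter, with 18242 tested, and the weight of the pseudocount.

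The other genes with the largest rises were Hsd3b6, Hbb-bh0, Pdzk1ip1, Myog, Kel, Stmn4, Ermap, Hapln1 and Mid1, with log2 fold changes from 0.97 (Mid1) to 2.28 (Hsd3b6). Kel and Ermap encode blood group proteins of red cells, and Hbb-bh0 is annotated as a globin pseudogene. The other genes with the largest falls were Ptgds, Dpt, Dhrs7c, Gipr, Depp1, Cavin4 and Cox8b, with log2 fold changes from -1.81 (Ptgds) to -1.24 (Cox8b). The cardiomyocyte list was not called (1 of 13 genes higher and 1 lower, camera adjusted p = 0.31). The erythroid list was not called either (camera adjusted p = 0.0601), with 3 of 17 genes higher, Hbb-bh1, Slc4a1 and Epb42 (6 adjusted over the list alone), and 0 lower. Sox9, a transcription factor of valve and cartilage progenitors, was higher by 0.58 ± 0.14 (log2, SE; adjusted p = 0.0377), at 4.92, 5.2, 3.4 and 3.01 FPKM in Adamts16+/- libraries 1 to 4 and 2.21 to 3.21 FPKM in WT. It did not pass without Adamts16+/- library 1, 2 or 3 (adjusted p = 0.143, 0.133 and 0.0576) or without WT library 1, 2, 5 or 6 (adjusted p = 0.0615, 0.0544, 0.0774 and 0.0658). Fn1 differed by 0.53 ± 0.18 (log2, SE) and did not pass the test (adjusted p = 0.132).

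By camera, 14 of the fixed lists differed between Adamts16+/- and WT, 7 in each direction. In the fatty acid list 4 of 21 genes fell (11 adjusted over the list alone), including Fabp4, Cd36, Fabp3 and Pdk4, and the list median was -0.30 (camera adjusted p = 4.57e-10; adjusted p = 0.182 with an estimated correlation). Of 35 oxidative phosphorylation genes 1 fell (1 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 3.25e-10; adjusted p = 0.634 with an estimated correlation); the mean log2 level was 5.92 to 6.19 in the Adamts16+/- libraries, 5.99 to 6.28 in WT libraries 1 to 4 and 6.45 to 6.67 in WT libraries 5 to 7. In the sarcomere list 2 of 24 genes fell, Myom2 and Tnni3 (4 adjusted over the list alone; camera adjusted p = 0.00228; adjusted p = 0.647 with an estimated correlation). The unfolded protein response and heat shock list had 5 of 19 genes higher (10 adjusted over the list alone), Hspa1a, Hsph1, Trib3, Calr and Hspa1b (camera adjusted p = 3.18e-07; adjusted p = 0.182 with an estimated correlation).

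The MAPK, Wnt and TGF-beta lists were called higher by camera, each with few members passing, and the Notch list was not called (0 of 19 passing, camera adjusted p = 0.909). In the MAPK and immediate early list 4 of 22 genes were higher (7 adjusted over the list alone), Spry4, Dusp6, Etv4 and Myc (camera adjusted p = 3.36e-05; adjusted p = 0.34 with an estimated correlation). Among Wnt pathway genes 2 of 27 were higher (6 adjusted over the list alone, and 1 lower), Rspo3 and Wnt5a (camera adjusted p = 3.36e-05; adjusted p = 0.347 with an estimated correlation). Among TGF-beta and BMP genes 2 of 31 were higher (6 adjusted over the list alone), Smad3 and Smad2 (camera adjusted p = 0.00108; adjusted p = 0.253 with an estimated correlation). Of 29 genes linked to the aortic valve, Gata5 and Smarca4 were higher (6 adjusted over the list alone; camera adjusted p = 0.00304; adjusted p = 0.615 with an estimated correlation). Valve mesenchyme markers Twist1, Hapln1 and Sox9 were higher and Postn fell by 0.41 (adjusted p = 0.05 after rounding), 3 of 16 higher and 1 lower (camera adjusted p = 0.0179; adjusted p = 0.634 with an estimated correlation). Valve mesenchyme and Wnt levels were highest in Adamts16+/- libraries 1 and 2 (mean log2 of 2.75 and 2.82 for valve mesenchyme, against 2.44 and 2.50 in libraries 3 and 4). The same libraries had higher lung markers (1.86 and 2.35 against 0.75 and 0.79), thymus markers (0.86 and 1.12 against 0.04 and 0.06) and markers of oesophagus, airway and skin epithelium (1.58 and 1.79 against at most 1.11). Among all libraries WT library 7 had the highest lung (4.29) and thymus (2.42) markers, with valve mesenchyme at 2.42. Markers of skeletal muscle, another tissue, were called as a list but were not raised in library 1 (mean log2 of 2.16 against 3.39, 2.75 and 3.13 in libraries 2 to 4): Myog and Acta1 were higher and Ckm lower among 9 genes, with a median of 0.51 (camera adjusted p = 0.0064; adjusted p = 0.406 with an estimated correlation).

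The remaining lists called by camera were lower in Adamts16+/- hearts. Mitochondrially encoded genes had a median of -0.11 with 0 of 13 passing (camera adjusted p = 0.0209; adjusted p = 0.752 with an estimated correlation), and ribosomal protein genes -0.16 with 0 of 40 passing (camera adjusted p = 0.000455; adjusted p = 0.766 with an estimated correlation). The mean log2 level of the ribosomal protein genes was 7.0 to 7.24 in the Adamts16+/- libraries and 6.94 to 7.24 in WT libraries 1 to 4, and higher in WT libraries 5 to 7 (7.29 to 7.83). Ventricular muscle markers Fhl2 and Pln fell, 2 of 10 (4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0367; adjusted p = 0.732 with an estimated correlation). Liver markers, from a tissue outside the heart, had a median of -0.38 with 0 of 8 passing (camera adjusted p = 0.0381; adjusted p = 0.766 with an estimated correlation); their mean log2 level was 0.80 to 1.52 in the Adamts16+/- libraries and 0.57 to 1.39 in WT libraries 1 to 4, and higher in WT libraries 5 to 7 (2.20 to 2.62).

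The count for Adamts16+/- depended on which WT libraries were used. It was 59 with WT libraries 5 to 7 left out and 2903 with WT libraries 1 to 4 left out, and it was 61, 78, 97 and 150 without Adamts16+/- library 1, 2, 3 or 4 and 171 and 229 without WT library 5 or 6. It was 0 with the planned erythroid covariate in limma, where the main count at an unadjusted p under 0.05 was 2974. The erythroid level (mean log2) was 5.64 to 6.07 in the Adamts16+/- libraries and 4.98 to 5.80 in WT. This covariate went partly with genotype, so the 0 does not show that blood accounts for the calls.

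**Figure D3:**
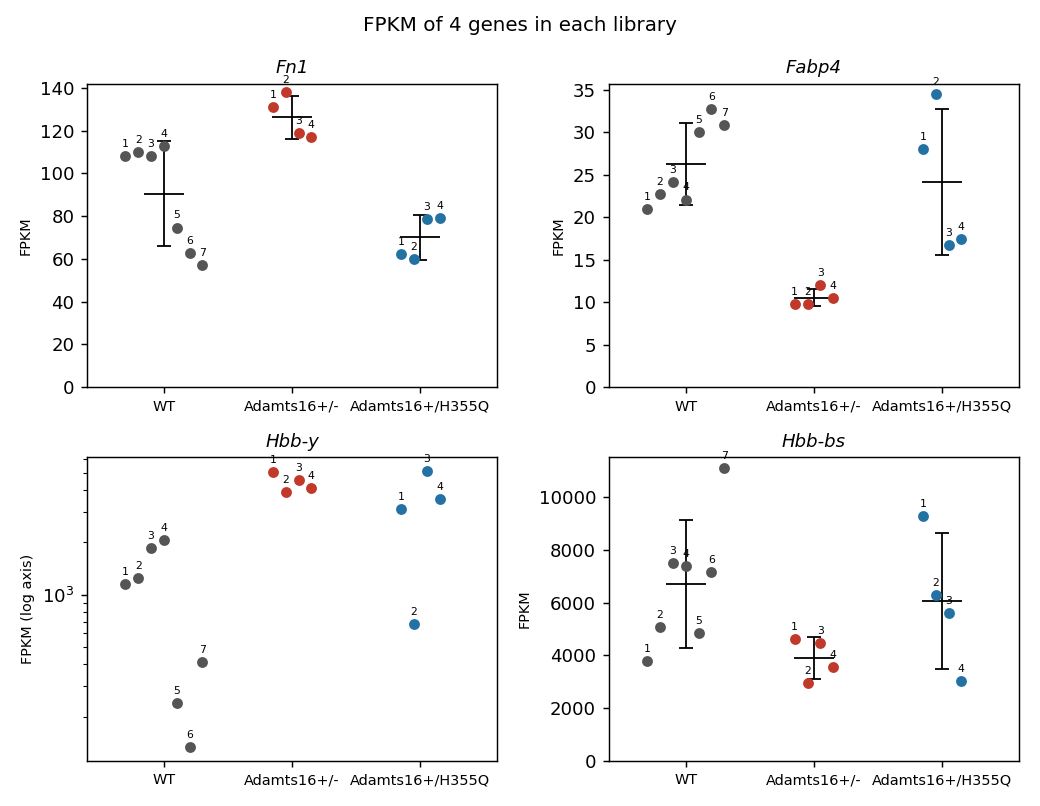
FPKM of Fn1, Fabp4, Hbb-y (log axis) and Hbb-bs in each library, numbered by replicate, with group mean and SD as bars on the linear axes. Fn1 in WT libraries 5 to 7 lies at 57.1 to 74.7 FPKM and in WT libraries 1 to 4 at 108 to 113 FPKM.

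In Adamts16+/H355Q hearts, Tbx5 and Col6a2 were lower than in WT and Hmgn2 was higher. The transcription factor Tbx5, required for atrial and septal development, fell by 0.63 on the log2 scale (adjusted p = 0.00791), from 13.5 ± 1.64 (SD, n = 7) to 8.48 ± 0.60 FPKM (SD, n = 4). The collagen VI chain Col6a2 fell by 0.60 (adjusted p = 0.0422), and Hmgn2, a nucleosome binding protein, was higher by 0.86 ± 0.10 (log2, SE; adjusted p = 0.00252), at 86.4 against 47.8 FPKM. In limma 57 of 15172 genes passed, 18 higher and 39 lower, and 2771 had an unadjusted p under 0.05. The balance of directions turned to 2105 higher and 1157 lower with WT libraries 5 to 7 left out, and to 1837 and 1017 with array weights. More genes stayed lower with median of ratios scaling (21 higher and 42 lower) and quantile normalization (43 and 74). The other named higher genes were Nadk, Tmem267, Pla2g16, Pgk1 and Prps1, from 0.29 (Prps1) to 0.48 (Nadk). The other named lower genes were Fndc1, Fmo2, Creb3l1, Susd2, Trabd2b, Lmntd1, Anpep and Mospd3, from -0.78 (Fndc1) to -0.52 (Mospd3). Fn1 was at -0.33 (adjusted p = 0.352) and Sox9 at -0.06 (adjusted p = 0.85).

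By camera 12 lists differed between Adamts16+/H355Q and WT, 4 higher and 8 lower. Collagens had a median of -0.25 with 1 of 23 lower (6 adjusted over the list alone; camera adjusted p = 2.67e-05; adjusted p = 0.64 with an estimated correlation). Of 30 matrix glycoprotein genes 0 passed over all genes (6 lower adjusted over the list alone; camera adjusted p = 0.000509; adjusted p = 0.64 with an estimated correlation). Of 20 ADAMTS family genes 2 were lower, Adamtsl4 and Adamts7 (2 adjusted over the list alone; camera adjusted p = 0.0204; adjusted p = 0.664 with an estimated correlation). In the atrial list 1 of 12 was lower, Tbx5 (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00372; adjusted p = 0.64 with an estimated correlation). Ribosomal protein genes had a median of 0.26 with 0 of 40 passing (camera adjusted p = 4.58e-06; adjusted p = 0.693 with an estimated correlation). Markers of the epicardium and fibroblasts (median -0.21, camera adjusted p = 0.0045), of the endothelium (median -0.13, camera adjusted p = 0.00855), elastic fibre genes (median -0.09, camera adjusted p = 0.0101) and mitochondrially encoded genes (median -0.16, camera adjusted p = 0.0204) were lower as lists, with 0 members passing in each. Oxidative phosphorylation (median 0.14, camera adjusted p = 0.00819), unfolded protein response and heat shock (median 0.19, camera adjusted p = 0.00855) and interferon genes (median 0.31, camera adjusted p = 0.00542) were higher as lists, again with 0 members passing. Adjusted over the list alone, 4 unfolded protein response and heat shock genes and 4 interferon genes were higher, and 3 epicardial, 1 endothelial and 2 elastic fibre genes lower. The interferon level was 2.26 (mean log2) in Adamts16+/H355Q library 2, and in the other 3 libraries (1.51 to 1.75) it lay within the WT range of 1.33 to 1.82. With an estimated correlation the adjusted p of these lists was 0.64 to 0.767.

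Several of these list levels in the Adamts16+/H355Q libraries overlapped 1 part of the WT libraries. The mean log2 level of ribosomal protein genes was 7.49 to 7.67, against 7.29 to 7.83 in WT libraries 5 to 7 and 6.94 to 7.24 in WT libraries 1 to 4. Oxidative phosphorylation was at 6.37 to 6.73, against 6.45 to 6.67 and 5.99 to 6.28, the endothelium at 3.70 to 3.80, against 3.67 to 3.93 and 4.01 to 4.04, and matrix glycoproteins at 3.46 to 3.69, against 3.55 to 3.65 and 3.72 to 3.84, in the same order. Epicardial and fibroblast markers, at 3.51 to 3.71, overlapped WT libraries 1 to 4 (3.59 to 3.81) and lay below WT libraries 5 to 7 (3.80 to 4.13).

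The count of 57 genes was 3262 with WT libraries 5 to 7 left out and 20 with WT libraries 1 to 4 left out. It was 1414 without WT library 7, 22 and 25 without WT library 2 or 3, 37 without Adamts16+/- library 1, and 21 without Adamts16+/H355Q library 3 and without library 4.

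Between the 2 genotypes, Fn1, Sox9 and Igfbp5 were higher and Fabp4 and Cox5a lower in Adamts16+/- hearts. Fn1 was higher by 0.85 ± 0.21 (log2, SE, adjusted p = 0.0238), at 126 ± 10.01 (SD, n = 4) against 70.1 ± 10.4 FPKM (SD, n = 4). The Adamts16+/H355Q libraries (59.8 to 79.3 FPKM) overlapped WT libraries 5 to 7 (57.1 to 74.7 FPKM). The Adamts16+/- libraries (117 to 138 FPKM) lay just above WT libraries 1 to 4 (108 to 113 FPKM). Much of this difference was thus also seen within WT, and Fn1 passed in neither comparison against WT. Sox9 was higher by 0.65 ± 0.16 (log2, SE; adjusted p = 0.0232), with 2.2, 1.89, 2.97 and 2.66 FPKM in the Adamts16+/H355Q libraries; it did not pass without Adamts16+/- library 1 or 2 (adjusted p = 0.0716 and 0.0713) or Adamts16+/H355Q library 1 or 2 (adjusted p = 0.0578 and 0.0756). Igfbp5, an insulin-like growth factor binding protein, was higher by 0.97 ± 0.17 (log2, SE; adjusted p = 0.0102). Fabp4 fell by 1.10 (adjusted p = 0.0111) and Cox5a, a subunit of cytochrome c oxidase, fell by 1.01 (adjusted p = 0.0179). In limma 1524 of 15172 genes passed, 867 higher and 657 lower in Adamts16+/-. The balance of directions turned to 1429 higher and 1592 lower with only the 2 groups compared, and to 2011 and 2341 with array weights. More genes stayed higher with median of ratios (872 higher and 823 lower) and TPM scaling (992 and 377). The other named higher genes were Bc1, Plagl2, Myog, Cacna2d2, Slc4a1, Zfp280b, Creb5, Kel and Srcap, from 0.91 (Srcap) to 2.48 (Bc1). The other named lower genes were Mir351, Ptgds, Rps21, Snord83b, H3f3c (annotated as a pseudogene), Tomm7, Rpl39 and Rps27, from -1.35 (Mir351) to -0.99 (Rps27).

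By camera 18 lists differed between the genotypes, 14 higher and 4 lower in Adamts16+/-. Oxidative phosphorylation genes were lower in 13 of 35 cases (26 adjusted over the list alone) and ribosomal protein genes in 7 of 40 (24 adjusted over the list alone), with medians of -0.44 and -0.45 (camera adjusted p = 1.02e-10 and 1.36e-09; adjusted p = 0.412 and 0.429 with an estimated correlation). Among TGF-beta and BMP genes 8 of 31 were higher (9 adjusted over the list alone), among aortic valve genes 7 of 29 (7 adjusted over the list alone) and among matrix glycoproteins 6 of 30 (11 higher and 1 lower adjusted over the list alone), with an adjusted p = 0.412 with an estimated correlation for each. The other lists called higher were collagens, proteoglycans, elastic fibre, matrix metalloprotease, integrin, MAPK and immediate early, Wnt, atrial, endothelial, erythroid and skeletal muscle genes, and the other lists called lower were fatty acid and interferon genes. Their adjusted p was 0.412 to 0.458 with an estimated correlation, so no list call held there. The ADAMTS family (camera adjusted p = 0.125) and Notch (camera adjusted p = 0.143) lists were not called. The implied depth of the 2 groups did not overlap, and the first principal component separated them as it separated the WT libraries. So did mt-Tq, at 18.4 to 23.2 FPKM in Adamts16+/- and 5.45 to 10 FPKM in Adamts16+/H355Q libraries (adjusted p = 0.19), and Mir6236, at 32.2 to 122 against 4.54 to 11 FPKM (adjusted p = 0.0502). The count was 3491 with WT libraries 5 to 7 left out, 2614 with WT libraries 1 to 4 left out, 657 with the Y-linked covariate and 4 with the erythroid covariate. The erythroid level (mean log2) was 5.64 to 6.07 in Adamts16+/- and 5.20 to 5.69 in Adamts16+/H355Q libraries, so that covariate went partly with genotype. The count was 379, 375 and 546 without Adamts16+/- library 1, 2 or 3, 633, 285, 1010 and 683 without Adamts16+/H355Q library 1, 2, 3 or 4, and 2485 without WT library 7.

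Both genotypes differed from WT in the same direction for 13 genes, 6 higher and 7 lower, and in opposite directions for 1 gene, Usp10, named after its values were seen (0.29 in Adamts16+/-, adjusted p = 0.0437; -0.36 in Adamts16+/H355Q, adjusted p = 0.043). The named ones were Fmo2, Fndc1, Kiz, Susd2, Pxmp4 and Adamtsl4, all lower; Adamtsl4 encodes a matrix protein related to the ADAMTS family and was at -0.31 (adjusted p = 0.0316) in Adamts16+/- and -0.47 (adjusted p = 0.0069) in Adamts16+/H355Q. Independent lists of these sizes would share 0.282 higher and 0.46 lower genes, but these lists use the same WT libraries, so those values are no reference for the 13. The 100 simulated data sets with unchanged groups against the same controls shared 0 genes. With means of 0.07 and 0.05 genes called per data set in the 2 comparisons, this 0 is no reference for the overlap. Genes were simulated independently, so the differences among the WT libraries that many genes share were left out. Across genes, which are not independent replicates, the fold changes correlated at 0.162 with a covariance of 0.00852, below the simulated 0.362 and 0.01 that shared controls alone gave. With WT libraries 1 to 3 as controls for Adamts16+/- and 4 to 7 for Adamts16+/H355Q the overlap was 0, and with the reverse it was 19.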

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

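Tests of length, depth, globins and the Adamts16 interval and counting error were chosen after the results were seen; the counts over other splits were planned. Of 291 groups of libraries examined for a single library apart from the rest, 16 had one, and chance alone gives about 1 in 20. The gap as a share of the range was 0.83 for Adamts16 in Adamts16+/- library 2 (highest), 0.873 for Gipr in Adamts16+/- library 3 (lowest), 0.872 for Tbx5 in Adamts16+/- library 3 (highest), 0.874 for Srcap in Adamts16+/- library 4 (lowest), 0.595 for Kel in WT library 4 and 0.605 for H3f3c in WT library 7 (both highest). Among list levels it was 0.645 for the cell cycle, 0.571 for interferon and 0.89 for thymus markers in WT library 7, 0.58 for collagens in WT library 3, and 0.684 for fatty acid and 0.622 for skeletal muscle genes in WT library 6, each highest. It was 0.83 for the cell cycle in Adamts16+/H355Q library 4, 0.832 and 0.864 for neural markers in Adamts16+/- library 2 and Adamts16+/H355Q library 2, and 0.955 for platelet markers in Adamts16+/- library 1, each highest.

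For the genes called between the 2 genotypes, the real grouping was the highest of 35 splits of the 8 libraries (1 of 35 as large), with 1524 genes against at most 3. This argues against a chance division of these libraries but cannot exclude it, because 1 of 35 is the smallest share these splits can give. Every other split mixed the 2 genotypes, which widens the spread within groups and can lower its count. Length and GC trends as the whole cause are argued against, since 1087 of the genes remained called with these trends removed. A difference in depth stays open: the implied fragments of the groups differed (exact permutation p = 0.0286). A library or litter batch that goes with genotype could account for it as well and cannot be separated from genotype by the labels, and the WT libraries lie on both sides of the same component. The genes mt-Tq and Mir6236, noticed after their values were seen, split the 2 genotypes without overlap, as they split WT libraries 1 to 4 from 5 to 7.

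Against WT, 4 of 100 splits gave as many genes as the 417 of Adamts16+/- and 3 of 100 as many as the 57 of Adamts16+/H355Q, the real ones included. The highest others were 1442 and 1559 genes, and such splits point to a structure of the samples that the labels do not give. For lists, chance is not excluded: 28 of 100 splits gave as many as the 14 lists (highest other 20), 48 of 100 as many as the 12 (highest other 25), and 8 of 35 as many as the 18 (highest other 24).

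The embryonic globin Hbb-bh1 and the globin pseudogene Hbb-bh0 were higher in Adamts16+/- than in WT, while Hbb-y (adjusted p = 0.0577) and Hba-x (adjusted p = 0.0502) did not pass in limma. This pattern was first noticed in fits on WT subsets chosen by their expression, which were withdrawn. More blood of the same make-up is argued against as the cause, since the adult Hba-a1 and Hbb-bs were not higher and differed from WT by -0.005 and -0.728. Embryonic relative to adult globin differed between the groups by 3.04 on the log2 scale (exact permutation p = 0.00909 over 330 splits). That p-value is no independent support, because the globins were picked after their values were seen in these libraries. A different make-up of the red cells stays open: the red cell genes Kel, Ermap, Slc4a1 and Epb42 were higher, while Alas2 (-0.335) was not. A younger developmental age may fit and stays untested, because no staging was used here. The fatty acid list, which rises as the heart matures, had a median of -0.302 in Adamts16+/- against WT. Its mean log2 level was 3.90 to 4.06 in the Adamts16+/- libraries and 4.25 to 4.48 in WT. In Adamts16+/H355Q libraries 1 to 4 it was 4.43, 4.35, 4.135 and 4.099, so libraries 3 and 4 lay below every WT library. The WT libraries spread widely in embryonic relative to adult globin, from -5.02 to -4.69 in libraries 1 to 4 and from -7.99 to -7 in libraries 5 to 7. The Adamts16+/- libraries lay from -3.08 to -2.73. The Adamts16+/H355Q libraries were at -4.9, -6.07, -3.56 and -3.21, so libraries 3 and 4 also lay above every WT library, and Hbb-bh0 differed from WT by 2.04 in this genotype (adjusted p = 0.0652) against 1.99 in Adamts16+/-.

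Adamts16 was not lower in the libraries labelled Adamts16+/-. Too few fragments are argued against as the reason: counting error alone gives a 95% margin of 0.0519 to either side if fragments are independent, less than the 0.132 of a halving. The spread between libraries could hide a halving, since the lower bound of the limma interval, -0.223, lies below -0.132. Whether the changed allele is still transcribed cannot be told apart from this with a value per gene, at a log2 difference of 0.024.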

How the results depend on the processing

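Settings that left out WT libraries, removed length and GC trends, kept protein-coding genes or used embryonic globins as a covariate were chosen after the data were examined; the others were planned. Counts below are for Adamts16+/- against WT (417), Adamts16+/H355Q against WT (57) and Adamts16+/- against Adamts16+/H355Q (1524), in that order where 3 are given, and the cause was not tested unless the setting itself tests fewer genes or libraries. Without the filter they were 157, 24 and 580, with only the 2 groups compared 274, 24 and 3021, with array weights 1058, 2854 and 4352, at an adjusted p under 0.1 994, 404 and 2964, and at an unadjusted p under 0.05 with a 1.5-fold change 229, 209 and 607. With the erythroid covariate they were 0, 88 and 4, and with the embryonic globin covariate 0, 1467 and 279, where limma called 2974 genes for the first at an unadjusted p under 0.05 without a covariate. Both covariates are measured outcomes that went partly with genotype. The embryonic globin Hbb-y was at 3870 to 5060 FPKM in Adamts16+/- and at 134 to 2070 FPKM in WT libraries. These counts therefore cannot tell an effect of blood from one of genotype. The Y-linked covariate gave 208 for the first and 657 for the third. TPM scaling gave 754 for the first (591 higher and 163 lower), with 18242 genes past the filter, and quantile normalization 117, trend removal 263 and protein-coding genes 37 for the second. With WT libraries 5 to 7 left out they were 59, 3262 and 3491, and with WT libraries 1 to 4 left out 2903, 20 and 2614. TPM scaling gave 992 higher and 377 lower genes between the genotypes. Median of ratios scaling gave 168 higher and 209 lower, and quantile normalization 192 higher and 241 lower, for Adamts16+/- against WT, where 238 were higher and 179 lower. Leaving out 1 library gave 61 to 463, 21 to 1414 and 285 to 2485 genes.

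The replicate numbers did not pair the libraries: same-numbered libraries deviated together with correlations from -0.23 to 0.21 over 12 pairs, and in 4 of 12 a library correlated best with its own number. A fit with the replicate number as a block, on libraries 1 to 4 of each group, called 15, 2758 and 2925 genes; it holds WT libraries 1 to 4 alone as controls.

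Lists called by camera were 14, 12 and 18. With an estimated correlation they were 0, 0 and 0, with smallest adjusted p-values of 0.182, 0.64 and 0.412, and with fry 6, 0 and 8. For Adamts16+/- against WT fry called the fatty acid, TGF-beta, MAPK, Wnt and skeletal muscle lists and the unfolded protein response and heat shock list. Their fry adjusted p was 0.00224 to 0.0458. Fry did not call the oxidative phosphorylation, sarcomere and ribosomal protein lists (fry adjusted p = 0.157, 0.159 and 0.505). Between the genotypes fry called the matrix glycoprotein, metalloprotease, integrin, TGF-beta, Wnt, aortic valve, oxidative phosphorylation and fatty acid lists. With WT libraries 1 to 4 left out camera called 7 lists for Adamts16+/H355Q against WT. Leaving out 1 library gave 11 to 16, 9 to 18 and 15 to 22 lists by camera. The overlap of 13 genes was 0 with WT libraries 1 to 3 for Adamts16+/- and 4 to 7 for Adamts16+/H355Q, and 19 with the reverse.

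The Adamts16 difference changed sign under several settings. For Adamts16+/- against WT it was -0.103 with quantile normalization, -0.15 with WT libraries 1 to 4 left out, 0.154 with WT libraries 5 to 7 left out, 0.23 with the embryonic globin covariate and -0.045 with trends removed. For Adamts16+/H355Q against WT it was -0.068 with quantile normalization and -0.002 with the Y-linked covariate. With WT libraries 1 to 4 left out it was -0.17, and with WT libraries 5 to 7 left out 0.134. Each of these 2 had an unadjusted exact permutation p of 0.0286, the smallest these group sizes allow, against 0.976 with all WT libraries. The WT subsets were set apart by expression, and Adamts16 itself was lower in WT libraries 1 to 4 than in 5 to 7. These p-values therefore do not test the genotype. Between the genotypes it was -0.035 with quantile normalization, -0.002 with array weights and -0.071 with trends removed. Leaving out 1 library gave -0.064 to 0.072, -0.026 to 0.052 and -0.068 to 0.06; the sign changed without Adamts16+/- library 2 (-0.064 and -0.068), WT library 1 (-0.006 and -0.026), WT libraries 2, 3 and 4 (-0.018, -0.016 and -0.012) and Adamts16+/H355Q libraries 1, 2 and 3 (-0.009, -0.011 and -0.013). The named genes gave 71 results, with a gene counted once for each comparison it was named in. Of these results 48 lost their call with the erythroid covariate, 41 with the embryonic globin covariate, 38 without the filter and 25 with the block. With WT libraries 5 to 7 left out 20 lost it, and with WT libraries 1 to 4 left out 18. Of 1065 values that left out 1 library, 265 lost a call. No called value reversed its sign. Sox9, not called in Adamts16+/H355Q against WT, went from -0.061 to 0.032 without Adamts16+/H355Q library 2.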

Other observations

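Most libraries carried both Xist, expressed from the inactive X chromosome of females, and the Y-linked gene Ddx3y. In WT library 1 they were at 51.2 and 8.91 FPKM, in Adamts16+/- library 2 at 47.9 and 9.56 FPKM, and in Adamts16+/H355Q library 3 at 47.5 and 9.4 FPKM. WT library 5 and Adamts16+/H355Q library 2 had Xist at 95.4 and 99.7 FPKM with Ddx3y at 0.0393 and 0 FPKM. WT libraries 4 and 6, Adamts16+/- library 1 and Adamts16+/H355Q library 4 had Xist at 0.0333, 0.12, 0.0327 and 0.0425 FPKM.

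Pole3, a subunit of DNA polymerase epsilon, was at 10.9, 11.4, 10.9 and 9.78 FPKM in WT libraries 1 to 4 and at 19.4 to 25.8 FPKM in the other 11 libraries. It was picked after its values were seen. With all WT libraries it did not pass in limma in any of the 3 comparisons (adjusted p = 0.235 for Adamts16+/- against WT, 0.192 for Adamts16+/H355Q against WT and 0.848 between the genotypes).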
